A study of Homo sapiens with 12 samples.

How the data were processed

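Messenger RNA levels were measured on 12 Illumina bead arrays, 1 array per sample, from SK-OV-3, a human ovarian cancer cell line. Per the labels, cells carried either a scrambled control shRNA (shCTRL) or an shRNA against IRF-1 (shIRF1), with or without 24 hours of CDDP (cisplatin, a platinum drug that crosslinks DNA), which gives 4 groups of 3 arrays. The dose of CDDP is not given in the sources used here. Per the labels, total RNA was extracted and turned into biotinylated cRNA with an Ambion messageAmp kit. Per the submitters' processing notes the arrays were processed with BeadStudio 2. The labels do not say that the 3 samples of a group came from separate cultures.

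The deposited table of non-normalized values holds, per the file headers, a mean bead signal for each probe, an intensity on a linear scale with no scaling between arrays. Beside each intensity it holds, per the file headers, a detection p-value of the probe against the negative controls of its array, as deposited. The authors' series matrix holds a further intensity for each probe on a linear scale. Each of its columns was a straight line of the same array's non-normalized signal (r = 1 on every array), with a factor between 1.37 and 2.66 and a constant between -116 and -14.2. What set those factors and constants stays unknown, while the linear scale, the lack of centring and the direction (brighter is higher) follow from that relation. The medians of the matrix columns were 122, 119.93 and 119 for shCTRL, 126, 123 and 132 for shCTRL with CDDP, 116, 117 and 119 for arrays labelled shIRF1, and 123, 119 and 116 for arrays labelled shIRF1 with CDDP.

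The files hold 47313 probes. Of these, 30109 have 1 gene symbol in the platform annotation, 8 have several, and 17196 are unnamed here. Symbols were brought up to date through the Entrez gene identifier for 30070 probes, with RefSeq gene names of assembly GRCh38.p14, which gave 20043 distinct symbols. The build behind the array annotation is not given in the sources used here, so the assembly was used for names and for the span of a gene, and no coordinates are reported. All columns of the deposited tables belonged to the 12 samples.

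Signals were normalized with neqc of limma 3.58.1 in R 4.3.3, which corrects the background by normexp with negative control statistics inferred from the detection p-values, adds an offset of 16, normalizes between arrays by quantiles and takes log2. Probes with a detection p-value under 0.05 on at least 3 arrays were kept, 22260 in all. Of several probes for 1 symbol, the probe with the highest mean over the 12 arrays was used, and probes without exactly 1 symbol stayed as features of their own. This left 17988 features, 12492 named genes and 5496 unnamed probes. A linear model with 1 mean per group was fitted over all 12 arrays with limma (lmFit and eBayes, 8 residual and 7.18 prior degrees of freedom), so that the 4 groups share an estimate of the spread. A feature was called when its two-sided p-value, adjusted by Benjamini-Hochberg over all features, was under 0.05. Adjusted p-values below are limma's unless camera is named. The 5 comparisons were shIRF1 against shCTRL without CDDP and with CDDP, CDDP against none under each shRNA label, and the interaction, which is the CDDP response under shIRF1 minus that under shCTRL.

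A set of 25 gene lists with 738 genes was written down, of which 684 genes are on the array and 606 were tested. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 25 lists, and again with an estimated correlation and with fry. The genes named were chosen by rule: IRF1 everywhere; in each comparison the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between the groups (for the interaction, called genes alone); and up to 4 members of each list, called members before others and then by size of change. Exceptions to the rule are the counts and means of small RNA genes, here and in the closing section, and the genes of RNA processing and PARN in the closing section. These were chosen after values had been seen. The groups, the models, the lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from 1 added alternative that left out the 2 arrays with the lowest array weights together.

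Where no array of a group detected any probe of a gene (detection p-value of 0.05 or more on all 3), the change is given as a bound. The brighter group's mean log2 value was set against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value among detected probes. An interaction that involves such a group was not read as a difference between responses. Called genes with several probes numbered 268, 173, 1211 and 1023 in the 4 pairwise comparisons, in the order above. A further probe of the same gene passed the test with the opposite sign for 0, 0, 11 and 7 of them.

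The model was tested on simulated data with 17988 features, of which 200 were changed in each of 5 runs. For shIRF1 without CDDP it recovered 9.85% of 1.5-fold, 65.4% of 2-fold and 100% of 4-fold changes. The shares were 6.87%, 64.5% and 100% for shIRF1 with CDDP, 9.85%, 62.7% and 100% for CDDP in shCTRL, 6.27%, 65.7% and 99.7% for CDDP in shIRF1, and 2.39%, 13.4% and 94.5% for the interaction. False calls made up 4.59%, 4.53%, 5.60%, 6.71% and 7.12% of the calls in the same order. Camera called 20 of 20 lists of 25 genes shifted by 0.5 on the log2 scale in the shIRF1 comparison without CDDP, and 0 of 480 unchanged lists. These simulated genes were drawn independently and the lists at random. The test therefore gives no rate of false calls for lists of correlated genes, where the estimated correlation reached 0.585 (mitosis genes). The 95% confidence intervals are those of the limma model, and the number of arrays limits the precision.

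Alternatives changed 1 choice at a time: no background correction, median scaling in place of quantiles, the series matrix, no detection filter or detection at 0.01 on all 12 arrays, every probe as a feature, only the arrays of the groups compared, array weights, a variance trend, the replicate number as a block, stricter thresholds, and leaving out each array in turn.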

Results

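Expression profiles were collected from SK-OV-3 cells, a human ovarian cancer line, under a control shRNA or an shRNA against IRF-1, each with and without CDDP (cisplatin), to describe the profile of cells that carry the shRNA against IRF-1. IRF-1 (gene IRF1) is a transcription factor of the interferon response. Each of the 4 groups held 3 arrays. Between 18075 and 21126 of the 47313 probes were detected per array (38.2% to 44.7%), with a mean signal of 259 to 388 and a median signal of 89.1 to 101. Arrays of the same group correlated at r = 0.974 to 0.987 over 12 pairs, against 0.921 to 0.979 over the 54 pairs from different groups, and no array was a copy of another. Because the labels do not state separate cultures, p-values measure the spread between these samples, which may be technical. The leading principal component held 49.8% of the variance and parted arrays with CDDP from those without, and the next held 16.6% and parted the shRNA labels.

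**Figure D1:**
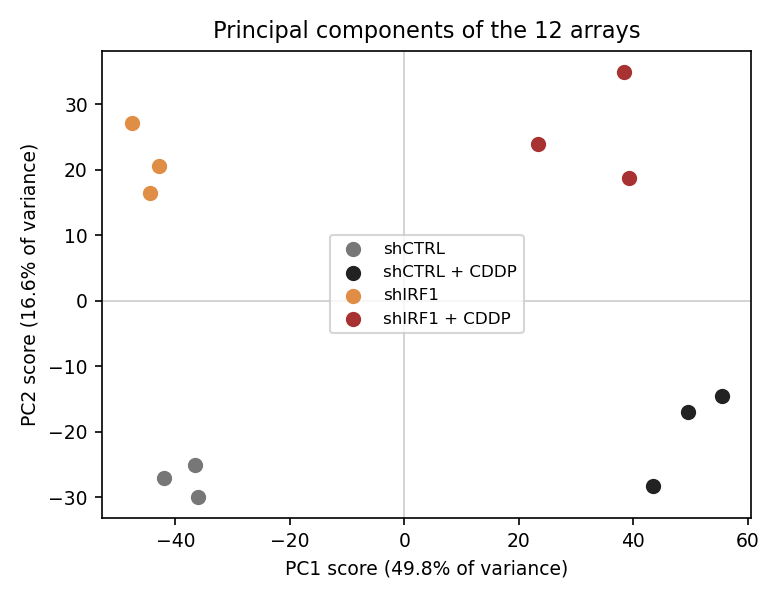
Scores of the 12 arrays on the principal components that hold 49.8% (horizontal axis) and 16.6% (vertical axis) of the variance, 1 point per array, coloured by group. The 6 arrays with CDDP lie on one side of the horizontal axis, and the shRNA labels part on the vertical axis.

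IRF1, the target of the shRNA, was measured by 1 probe that was detected on all 12 arrays. Its log2 level was 8.30, 8.51 and 7.84 on the shCTRL arrays and 8.59, 8.14 and 8.20 on the arrays labelled shIRF1. With CDDP it was 9.97, 10.38 and 9.38 under shCTRL and 8.94, 9.08 and 9.26 on arrays labelled shIRF1. Without CDDP the group means were 8.21 ± 0.34 and 8.31 ± 0.25 (SD, n = 3 each), a difference of 0.10 (SE 0.25, 95% confidence interval -0.43 to 0.62, limma adjusted p = 0.902). IRF1 was thus not measurably lower where the label says it was targeted, and the samples are called arrays labelled shIRF1 throughout. With CDDP the means were 9.91 ± 0.50 and 9.09 ± 0.16 (SD, n = 3 each). The 3 arrays labelled shIRF1 lay below the 3 others by a mean of 1.77-fold (log2 -0.82, SE 0.25, interval -1.34 to -0.30). Adjusted over all features this did not pass (limma adjusted p = 0.0811). Its unadjusted limma p was 0.00453, for a gene whose check was planned beforehand. That difference passed with shCTRL CDDP array 3 left out (-1.08, adjusted p = 0.0209), in the series matrix values (-0.84, 0.0343), without background correction (-0.75, 0.043) and with a variance trend (-0.82, 0.0442), over a range of adjusted p from 0.0209 to 0.239 across its alternatives.

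CDDP raised IRF1 3.24-fold under shCTRL (log2 1.70, SE 0.25, interval 1.17 to 2.22, limma adjusted p = 0.000105) and 1.72-fold on arrays labelled shIRF1 (0.78, SE 0.25, interval 0.26 to 1.31, adjusted p = 0.0328). The test of the difference between these rises gave -0.92 (SE 0.35, interval -1.66 to -0.17). It did not pass adjusted over all features (limma adjusted p = 0.502), with an unadjusted limma p of 0.0188. The smaller rise lost its call with shIRF1 array 2 (0.70, adjusted p = 0.107), shIRF1 CDDP array 2 (0.79, 0.0793), shIRF1 array 3 (0.73, 0.0925) or shIRF1 CDDP array 3 (0.70, 0.101) left out, with median scaling (0.79, 0.0797) and without the detection filter (0.78, 0.0692). Its adjusted p over all alternatives ran from 0.014 to 0.107.

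**Figure D2:**
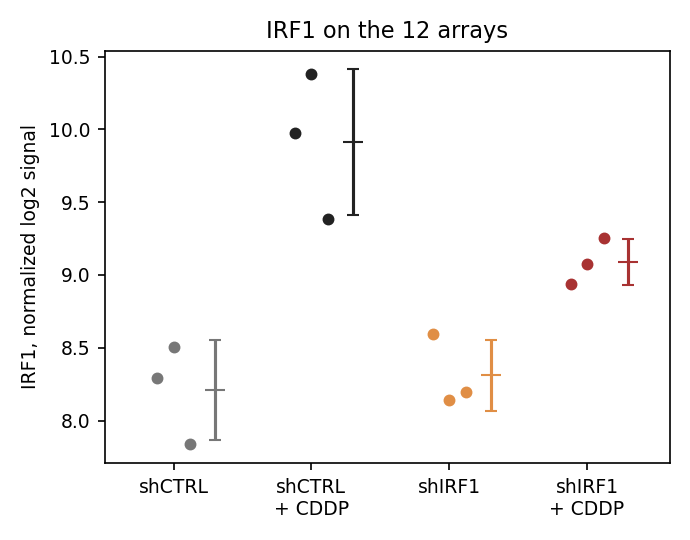
IRF1 level on each of the 12 arrays (points, log2 normalized signal) by group, with group means and SD (n = 3). The shCTRL arrays with CDDP lie at 9.38 to 10.38, the arrays labelled shIRF1 with CDDP at 8.94 to 9.26, and the 6 arrays without CDDP at 7.84 to 8.59.

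Without CDDP, 32 of 159 small RNA genes and 8 of 14 histone genes were higher on arrays labelled shIRF1 than under shCTRL, and 1 and 0 were lower. The small RNA genes were made a group only after values had been seen. E-cadherin (CDH1), the adhesion protein of epithelial cells, was 8.50-fold higher (log2 3.09, SE 0.23, limma adjusted p = 1.48e-06), and SNAI2 (Slug), a repressor of E-cadherin transcription, was 5.98-fold lower (-2.58, SE 0.19, adjusted p = 1.25e-06). The largest rises also held chromogranin A (CHGA, a protein of neuroendocrine granules, 17.7-fold, log2 4.15, SE 0.66), DEPTOR, an inhibitor of the mTOR kinase (11.4-fold, 3.51, SE 0.17), the matrix protease MMP7 (2.90, SE 0.25) and WDR72 (2.91, SE 0.34). The largest fall was that of SERPINB5, the serpin maspin, at 17.6-fold (-4.13, SE 0.21, adjusted p = 1.41e-08). It was followed by the semaphorin SEMA6A (-2.85), MMP28 (-2.81), FAM83A (-2.74), the Wnt antagonist DKK1 (-2.74), the proteoglycan SPOCK1 (-2.70) and the centromere protein CENPW (-2.64). CGB5 and CGB1, near-identical copies of the chorionic gonadotropin beta gene, fell by 2.76 and 2.68, and SPANXA1 fell by 2.69. Probes of such copies may share targets, so which copy changed is uncertain. Another MMP28 probe changed by 0.10 (adjusted p = 0.913). IRF1 itself did not differ here, so these directions rest on the labels.

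Small RNAs made up 5 of the 10 largest rises. The guide RNAs SCARNA18 and SCARNA13, which direct the modification of spliceosomal RNAs, rose by log2 3.71 (SE 0.18) and 2.80 (SE 0.23). SCARNA8 and SCARNA11 were at least 13.3-fold and 12.8-fold higher, and SNORA79 at least 7.61-fold. These 3 were not detected on any shCTRL array, so their folds are lower bounds that set the brighter group against the lowest signal of a detected probe. The mean over all 79 SCARNA and SNORA genes tested was 5.15 to 5.27 on the shCTRL arrays and 5.94 to 5.98 on arrays labelled shIRF1 without CDDP, and 5.44 to 5.63 against 6.17 to 6.54 with CDDP.

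In all, 1051 features were called in this comparison, 557 higher and 494 lower on arrays labelled shIRF1, of which 282 and 226 changed at least 2-fold. The arrays of the groups did not overlap for 1050 of them. Over all features, 25.1% did not overlap, where chance gives 10%. The count fell to 626, 585 and 636 with shCTRL array 1, shIRF1 array 1 or shCTRL array 3 left out, and to 499 with median scaling.

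Among the lists, the histone genes rose most. Of 14 measured, 8 rose, 0 fell and 6 did not pass, with a median of 0.92 (11 rose adjusted over the list alone). H2AC18, H2AC19 and H2AC20, near-identical H2A genes whose probes may not tell them apart, rose by 2.13, 1.88 and 1.65, and H2BC12 rose by 1.55 (SE 0.21). The list's camera adjusted p was 3.1e-10, within a range of adjusted p from 8.95e-13 to 0.0185 over its alternatives, the highest with an estimated correlation, so this call held. The array means of this list and of the small RNA genes moved with the shRNA label alike, the histone mean from 6.97 to 7.09 on shCTRL arrays to 7.91 to 8.13 on arrays labelled shIRF1. The other 7 lists called at the preset correlation were not called with an estimated correlation.

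Epithelial, mesenchymal and TGF-beta genes fell as a list, with 8 of 27 lower, 1 higher (CDH1) and 18 not passed (11 lower and 2 higher adjusted over the list alone, median -0.38). The camera adjusted p was 0.000122, with adjusted p from 1.49e-06 to 0.0702 over the alternatives, the highest with an estimated correlation. Besides SNAI2, the matrix proteins SPARC (-1.92, SE 0.31) and THBS1 (-1.41, SE 0.19) were lower. The list pools epithelial with mesenchymal and TGF-beta genes, so its shift does not say that epithelial genes fell. S phase and E2F target genes lay lower as a group, 37 of 38 with a negative change and a median of -0.46, although only 4 passed (12 adjusted over the list alone, all lower). Its camera adjusted p was 9.44e-11, with adjusted p from 1.7e-15 to 0.186 over the alternatives, the highest with an estimated correlation. Among the 4 were UHRF1, a DNA methylation maintenance factor (-1.19, SE 0.18), and the primase subunit PRIM1 (-0.89, SE 0.18). Another UHRF1 probe changed by -0.35 (limma adjusted p = 0.614), and the PRIM1 call was lost with median scaling (-0.92, adjusted p = 0.0575, against 0.00219 at its lowest). Cholesterol synthesis genes rose by a median of 0.40, 4 of 19 higher and 15 not passed (4 adjusted over the list alone). The list's camera adjusted p was 0.000199, with adjusted p from 2.98e-06 to 0.156 over the alternatives, the highest with an estimated correlation. The 4 included TM7SF2 (1.37, SE 0.29) and DHCR7 (0.90, SE 0.19), enzymes of late steps, whose calls were lost without shCTRL array 1 (1.20, adjusted p = 0.0522, the highest over its alternatives, with 0.00361 the lowest) and shCTRL array 2 (0.80, 0.0538), respectively. With median scaling DHCR7 had an adjusted p of 0.126, against 0.00364 at its lowest, and another DHCR7 probe changed by 0.66 (0.086).

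NF-kB and inflammatory cytokine genes had a median of 0.37, with 4 of 21 higher, 1 lower and 16 not passed (the same counts adjusted over the list alone), led by the cytokine TNF, at least 3.89-fold higher. Its camera adjusted p of 0.0151 became 0.126 without shIRF1 array 1, and 0.000691 to 0.587 over all alternatives, the highest adjusted p with an estimated correlation. Antigen presentation genes (median -0.19, 0 of 16 passed by limma, also adjusted over the list alone, with 5 at an unadjusted p under 0.05), mitosis genes (-0.16, 1 of 45 lower, 0 adjusted over the list alone) and DNA crosslink repair genes (-0.11, 3 of 35 lower, also adjusted over the list alone) were called with camera adjusted p of 0.0435, 0.0435 and 0.0464. With an estimated correlation these became adjusted p of 0.52, 0.753 and 0.186, the highest over their alternatives, where the lowest were 0.00739, 3.22e-05 and 0.0174. The antigen presentation call was lost without shCTRL array 1, shCTRL array 2, shIRF1 array 2 or shIRF1 array 3 (adjusted p 0.0791, 0.0921, 0.0992 and 0.143). The mitosis call was lost without shIRF1 array 1 or shIRF1 array 3 (0.518 and 0.226), and its direction turned without shCTRL array 2 (0.577). The crosslink repair call was lost without shIRF1 array 1, shIRF1 CDDP array 1, shCTRL array 2 or shIRF1 array 3 (0.0838, 0.055, 0.182 and 0.0771). Of 12 other alternatives, the antigen presentation, mitosis and crosslink repair calls were lost in 5, 5 and 8. For each these included detection at 0.01 on all 12 arrays, only the groups compared and array weights. For crosslink repair they also included no background correction, median scaling and the series matrix.

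Described IRF-1 targets were not called as a list (median 0.08, 5 of 19 higher, 1 lower and 13 not passed, the same adjusted over the list alone, camera adjusted p = 0.0597). Those that rose included the death ligand TNFSF10 (TRAIL, 3.81-fold, log2 1.93, SE 0.37), the tryptophan-degrading enzyme IDO1 (3.29-fold, 1.72, SE 0.27) and the guanylate-binding protein GBP2 (2.64-fold, 1.40, SE 0.22). Interferon-stimulated genes were not called either (5 of 43 higher, 1 lower and 37 not passed, the same adjusted over the list alone, camera adjusted p = 0.13).

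With CDDP in both groups, the same comparison again had CDH1 higher (6.02-fold, log2 2.59, SE 0.23, limma adjusted p = 6.81e-06) and SNAI2 lower (3.58-fold, -1.84, SE 0.19) on arrays labelled shIRF1. SCARNA11 (4.06), SCARNA8 (3.75), SCARNA18 (3.42), SNORA79 (2.94), SCARNA23 (2.67) and SNORA63 (2.56) were among the 10 largest rises, with the spliceosomal RNA RNU4-2 (2.52) and PCCA, a subunit of propionyl-CoA carboxylase (2.77). CHGA was 10.3-fold higher (3.36, SE 0.66, adjusted p = 0.00874), a call lost without shIRF1 CDDP array 3 (2.70, adjusted p = 0.0538, against 0.000265 to 0.0538 over all alternatives). SERPINB5 was at least 9.99-fold lower, the keratins KRT16 and KRT14 at least 7.25-fold and 6.84-fold, and the trypsinogen gene PRSS3 at least 6.02-fold, each undetected on every array labelled shIRF1 with CDDP. FAM83A (-3.07), SPOCK1 (-3.06), ESM1 (-2.55), SPARC (-2.40) and the copies SPANXA1 (-2.55) and CGB5 (-2.45) were lower too. KRT16, KRT14 and PRSS3 have close copies, so their identity is uncertain as well.

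Here 692 features were called, 296 higher and 396 lower, of which 139 and 191 changed at least 2-fold. Over all features, 21.2% did not overlap between the groups, where chance gives 10%. The count fell to 394 and 356 with shIRF1 CDDP array 1 or shIRF1 CDDP array 3 left out, to 329 with only the groups compared in the model, and to 310 with median scaling, which also moved the share of higher calls from 42.8% to 56.8%.

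The lists called with CDDP were epithelial and mesenchymal genes (median -0.49, 6 of 27 lower, 1 higher and 20 not passed, 10 lower and 1 higher adjusted over the list alone, camera adjusted p = 5.93e-05), histone genes (0.56, 2 of 14 higher and 12 not passed, 5 adjusted over the list alone, 5.93e-05), antigen presentation genes (-0.30, 3 of 16 lower and 13 not passed, 7 adjusted over the list alone, 0.00279) and mitosis genes (0.17, 1 of 45 higher and 44 not passed, 1 adjusted over the list alone, 0.0205). With an estimated correlation their adjusted p was 0.0844, 0.0844, 0.312 and 0.682, the highest over their alternatives, where the lowest were 8.56e-07, 2.21e-05, 6.13e-06 and 0.00213. The mitosis call was lost without shCTRL CDDP array 2 or shIRF1 CDDP array 3 (camera adjusted p = 0.145 and 0.107). The histone mean was 7.66 to 8.02 on shCTRL arrays with CDDP and 8.30 to 8.47 on arrays labelled shIRF1 with CDDP, where the small RNA mean was 5.44 to 5.63 and 6.17 to 6.54. Among the interferon-stimulated genes, which were not called as a list (0 of 43 higher, 3 lower and 40 not passed, 4 lower adjusted over the list alone, camera adjusted p = 0.12), IFIT2 was 2.28-fold lower (-1.19, SE 0.22, limma adjusted p = 0.00484). Described IRF-1 targets had a median of 0.01, with 2 of 19 higher, 1 lower and 16 not passed (the same adjusted over the list alone, camera adjusted p = 0.964).

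Between the arms without and with CDDP, 364 features were called in both shIRF1 comparisons, 155 higher and 205 lower in both and 4 in opposite directions, where independent lists of these lengths would share 9.17 and 10.9. The changes correlated across features at r = 0.558 (covariance 0.0952), features not being independent replicates, and these comparisons share no array. Simulated unchanged groups gave r = 0.00056.

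CDDP under shCTRL raised genes of the stress, inflammatory and p53 responses together. The largest rise was that of ATF3, a stress-induced transcription factor, at 40.8-fold (log2 5.35, SE 0.22, limma adjusted p = 3.18e-09). The cytokine TNF rose at least 35.5-fold, the interleukin IL6 33.3-fold (5.06, SE 0.29), CXCL2 24.9-fold (4.64, SE 0.41), the cell cycle inhibitor CDKN1A (p21) 22.7-fold (4.51, SE 0.30) and the NF-kB inhibitor TNFAIP3 20.2-fold (4.34, SE 0.26). CXCL8 (4.30), FOSB (4.25), CCL20 (4.21) and the growth factor HBEGF (4.15) followed. The largest falls were those of ZMIZ1 (18.1-fold, -4.18, SE 0.27), NTNG1 (-4.09), VAV3 (-3.72), AGAP1 (-3.59), WDR70 (-3.56), the receptor phosphatase PTPRK (-3.54), TENM3 (-3.43), CLEC16A (-3.37) and FARS2 (-3.31), with NLGN4X at least 6.87-fold lower.

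On arrays labelled shIRF1 the largest rises with CDDP were ATF3 (34.7-fold, 5.12, SE 0.22, limma adjusted p = 3.05e-09), HBEGF (4.58), CCL20 (4.30), IL6 (4.16), TNF (4.07), CDKN1A (3.99), CXCL8 (3.90), TNFAIP3 (3.85), SLC25A24 (3.78) and FOSB (3.66). ZMIZ1 (-3.67), VAV3 (-3.63), AGAP1 (-3.75), TENM3 (-3.70), FARS2 (-3.67) and PTPRK (-3.55) were among the 10 largest falls again, and NTNG1 was at least 10.03-fold lower. The others were NCALD (-4.09), CUX1 (-3.85) and DEPTOR (-3.79), where 1 and 2 of the 3 arrays labelled shIRF1 with CDDP detected NCALD and DEPTOR. Further probes disagreed with the size of some of these changes. In shCTRL another probe of CDKN1A changed by 0.40 (limma adjusted p = 0.245), of AGAP1 by -0.39 (0.21) and of NLGN4X by -0.63 (0.0614), and on arrays labelled shIRF1 another of CDKN1A changed by 0.29 (0.459) and of CUX1 by -0.82 (0.00938). Another SLC25A24 probe changed by 0.04 (0.941), and the gene was read from that probe with detection required on all 12 arrays, where its adjusted p was 0.925 (1.84e-10 to 0.925 over its alternatives).

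In shCTRL 4849 features were called with CDDP, 2425 higher and 2424 lower, and 40.2% of all features did not overlap, where chance gives 10%. On arrays labelled shIRF1 3960 were called, 1890 higher and 2070 lower, and 36.9% did not overlap. In both, 1353 features were higher and 1579 lower, with 9 in opposite directions, where independent lists would share 255 and 279, and the changes correlated across features at r = 0.826 (covariance 0.349) with no shared array (simulated r = -0.00006). Median scaling gave 2983 calls in shCTRL, 37.4% of them higher in place of 50.0%, and 2226 on arrays labelled shIRF1.

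Across genes, which are not independent replicates, long genes fell more with CDDP. Over 11771 protein-coding genes the rank correlation between the span of the gene and its change was -0.499 in shCTRL and -0.438 on arrays labelled shIRF1. In the tenth of genes with the longest span 64.3% and 60.4% fell and 0.850% rose in each arm, while in the tenth with the shortest 3.31% and 4.58% fell and 24.7% and 18.7% rose. The choice of this measure came after long genes had been noticed among the largest falls. Neither the list tests nor the changes of single genes with CDDP were adjusted for gene span.

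Of the lists, NF-kB and inflammatory cytokine genes moved most with CDDP. In shCTRL 18 of 21 rose and 3 did not pass (18 adjusted over the list alone, median 1.92, camera adjusted p = 1.13e-13), and on arrays labelled shIRF1 16 rose and 5 did not pass (17 adjusted over the list alone, 1.89, 3.43e-15). Immediate early and AP-1 genes followed, with 14 of 21 higher and 7 not passed in each arm (15 and 14 adjusted over the list alone, medians 1.41 and 1.25, camera adjusted p = 2.31e-10 and 8.2e-12), including FOS (3.12 and 2.40, SE 0.20) and KLF4 (2.95 and 2.61, SE 0.27). Of the integrated stress and unfolded protein response 17 of 25 rose in each arm, with 0 and 1 lower and 8 and 7 not passed (18 and 17 higher, 1 and 3 lower adjusted over the list alone, medians 1.01 and 0.90, 3.46e-10 and 4.23e-09). DDIT3 (CHOP), an effector of that response, rose by 3.72 and 2.98 (SE 0.20), and PPP1R15A by 2.82 and 2.95 (SE 0.24). Of the p53 targets 10 and 14 of 26 rose, with 1 lower in each arm and 15 and 11 not passed (10 and 14 higher, 1 and 2 lower adjusted over the list alone, medians 0.49 and 0.66, camera adjusted p = 0.000188 and 1.37e-05). The proapoptotic gene PMAIP1 (NOXA) rose by 3.90 and 3.38 (SE 0.26), and GADD45A by 2.49 and 3.08 (SE 0.20). These 4 lists kept their calls in both arms with an estimated correlation, with adjusted p of 0.0496 and 0.0375, 0.0377 and 0.0269, 0.00439 and 0.00693, and 0.0377 and 0.0265 in the order above, each the highest over that list's alternatives, where the lowest ran from 9.75e-26 to 1.04e-05.

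S phase and E2F target genes rose with CDDP, 17 of 38 in shCTRL (2 lower, 19 not passed, 19 and 2 adjusted over the list alone, median 0.51, camera adjusted p = 4.93e-05) and 30 of 38 on arrays labelled shIRF1 (1 lower, 7 not passed, 34 and 1 adjusted over the list alone, 0.88, 6.25e-15). Neither call held with an estimated correlation (adjusted p = 0.386 and 0.0873), the highest over the alternatives, where the lowest were 3.13e-07 and 7.5e-24. Cyclin E (CCNE1) rose by 2.12 and 1.90 (SE 0.28), E2F2 by 2.08 and 1.97 (SE 0.24) and the nuclease EXO1 by 1.67 and 1.99 (SE 0.21), while another CCNE1 probe changed by -0.19 and 0.24 (limma adjusted p = 0.665 and 0.616). Mitosis genes fell in shCTRL (12 of 45 lower, 2 higher and 31 not passed, 14 and 3 adjusted over the list alone, median -0.24, camera adjusted p = 0.0212), among them the kinesin KIF11 (-1.21, SE 0.27) and the kinase PLK1 (-1.19, SE 0.30). The adjusted p was 0.676 with an estimated correlation, 0.624 without shCTRL array 2, and 0.00101 at its lowest. On arrays labelled shIRF1 mitosis genes were not called (7 of 45 higher, 2 lower and 36 not passed, 5 and 1 adjusted over the list alone, camera adjusted p = 0.669), and the kinase CDK1 rose by 1.24 (SE 0.24).

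Histone genes, described IRF-1 targets and antigen presentation genes were called with CDDP in shCTRL, but not with an estimated correlation (adjusted p = 0.099, 0.0646 and 0.342, within ranges over the alternatives of 0.00022 to 0.099, 0.00181 to 0.141 and 0.000326 to 0.342). The IRF-1 target call was also lost without the detection filter and with detection at 0.01 on all 12 arrays. Of the histone genes 9 of 14 rose, 1 fell and 4 did not pass (the same adjusted over the list alone, median 0.86, camera adjusted p = 0.00182), and the mean of the SCARNA and SNORA genes was 5.15 to 5.27 without and 5.44 to 5.63 with CDDP. Of the IRF-1 targets 8 of 19 rose and 11 did not pass (8 higher and 1 lower adjusted over the list alone, 0.40, 0.00748), with prostaglandin synthase PTGS2 at least 7.12-fold and the guanylate-binding protein GBP1 2.73-fold (1.45, SE 0.22). Of the antigen presentation genes 4 of 16 rose and 12 did not pass (6 adjusted over the list alone, 0.35, 0.0104), with the peptide transporters TAP1 (1.19, SE 0.22) and TAP2 (1.01, SE 0.16), where another TAP2 probe changed by -0.31 (limma adjusted p = 0.6). On arrays labelled shIRF1 these lists were not called (4 of 14 higher and 1 lower, 6 of 19 higher and 4 lower, and 2 of 16 higher; 6 and 1, 8 and 4, and 2 and 0 adjusted over the list alone; camera adjusted p = 0.0729, 0.127 and 0.0586), and the ovarian and epithelial tumour markers were (7 of 18 lower and 11 not passed, 7 adjusted over the list alone, median -0.26, 0.0242), with the keratin KRT19 (-1.98, SE 0.23) and the transcription factor PAX8 (-1.29, SE 0.21). The marker call was lost without shIRF1 CDDP array 2 (adjusted p = 0.0519) and with an estimated correlation (adjusted p = 0.252), against 0.00209 at its lowest. In shCTRL KRT19 and PAX8 fell by 2.17 and 1.53, and 5 of 18 markers were lower, 1 higher and 12 not passed (the same adjusted over the list alone, camera adjusted p = 0.168). Other PAX8 probes changed by -0.49 and -0.38 in shCTRL (limma adjusted p = 0.0721 and 0.192) and by -1.56 and -0.45 on arrays labelled shIRF1 (3.37e-05 and 0.138).

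**Figure D3:**
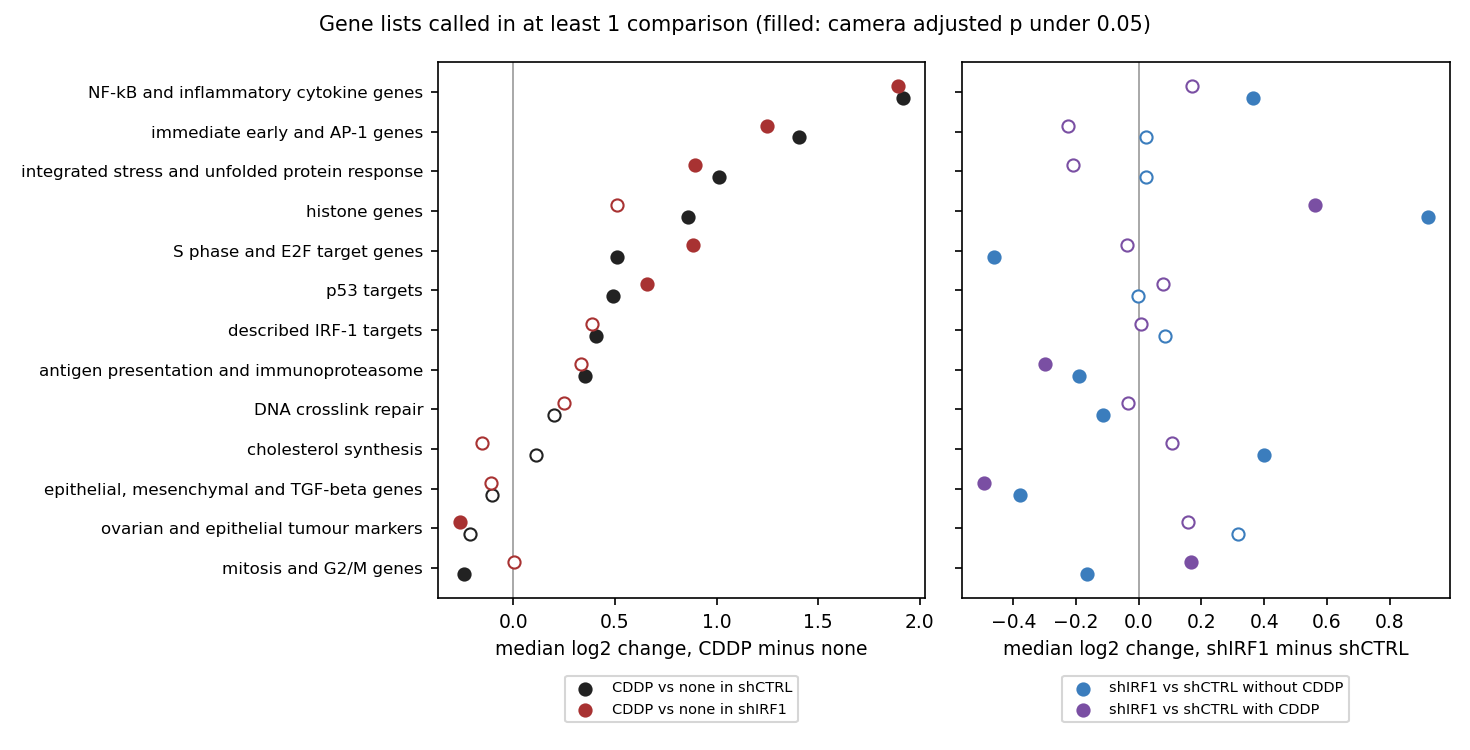
Median log2 change of the members of each gene list called in at least 1 pairwise comparison. The left panel gives CDDP minus none (black in shCTRL, red on arrays labelled shIRF1) and the right panel shIRF1 minus shCTRL (blue without and purple with CDDP), and filled points mark a camera adjusted p under 0.05. NF-kB genes lie highest with CDDP (1.92 and 1.89), and histone genes highest on arrays labelled shIRF1 (0.92 and 0.56).

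The interaction, which tests whether the CDDP response differed between the shRNA labels, called 12 features of 1455 with an unadjusted p under 0.05 (899.4 by chance), 1 higher and 11 lower. Of these 9 were named genes, of which 4 were detected on all 12 arrays and had a lower CDDP response on arrays labelled shIRF1. IFIT2, an interferon-induced RNA-binding protein, rose by log2 1.74 with CDDP in shCTRL, against -0.35 on arrays labelled shIRF1, which did not pass (interaction -2.09, SE 0.30, limma adjusted p = 0.0153). TSC22D3 (GILZ), a gene induced by glucocorticoids, rose by 2.02, against 0.36, which did not pass (-1.66, SE 0.24, 0.0153). AKAP19 (-1.995, adjusted p = 0.0153) and IER5L (-1.88, 0.0153) rose in shCTRL, by 0.86 and 1.31, and fell by 1.14 and 0.56 on arrays labelled shIRF1. Another probe of TSC22D3 gave an interaction of -1.25 (adjusted p = 0.471). All 4 were already higher on arrays labelled shIRF1 without CDDP. IER5L was higher by 1.43, AKAP19 by 1.39, IFIT2 by 0.91 and TSC22D3 by 0.79 (limma adjusted p = 0.00029, 0.000655, 0.0196 and 0.0119). With CDDP IFIT2 (-1.19) and TSC22D3 (-0.87) were lower, while AKAP19 (-0.60, adjusted p = 0.128) and IER5L (-0.45, 0.231) did not pass. The interactions thus rest in part on a higher level without CDDP.

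The other 5 genes passed the test (limma adjusted p = 8.75e-05 for DEPTOR, 0.0153 for MPPED2, 0.0289 for LMO3, 0.0205 for the calcium channel CACNA1H and 0.0411 for NCALD), but 0 of 3 shCTRL arrays with CDDP detected them. Their response in shCTRL has therefore no measured size, and neither a difference between the responses nor its direction is established for them. In shCTRL DEPTOR was at least 1.29-fold and NCALD at least 4.04-fold lower with CDDP, and MPPED2, LMO3 and CACNA1H were not detected without CDDP either, so they have no fold there. The count of 12 became 3, 3, 4, 2, 6 and 2 with shCTRL array 1, shCTRL CDDP array 1, shIRF1 CDDP array 1, shCTRL CDDP array 2, shIRF1 CDDP array 2 or shCTRL array 3 left out, 23 in the series matrix values, 19 with array weights and 5 with detection required on all 12 arrays. DEPTOR kept its call in every alternative that tested it (adjusted p 1.35e-05 to 0.0018), and each of the other 8 lost it without 4 to 11 of the 12 arrays and in at least 1 other alternative. Over all alternatives the adjusted p reached 0.0727 for IFIT2 (without shCTRL CDDP array 2) and, with median scaling, 0.0797 for IER5L, 0.22 for AKAP19, 0.242 for TSC22D3 and 0.53 for NCALD. Without background correction it reached 0.0907 for MPPED2, 0.116 for CACNA1H and 0.148 for LMO3. The lowest adjusted p of these 8 genes ran from 0.00223 for TSC22D3 to 0.0147 for LMO3.

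**Figure D4:**
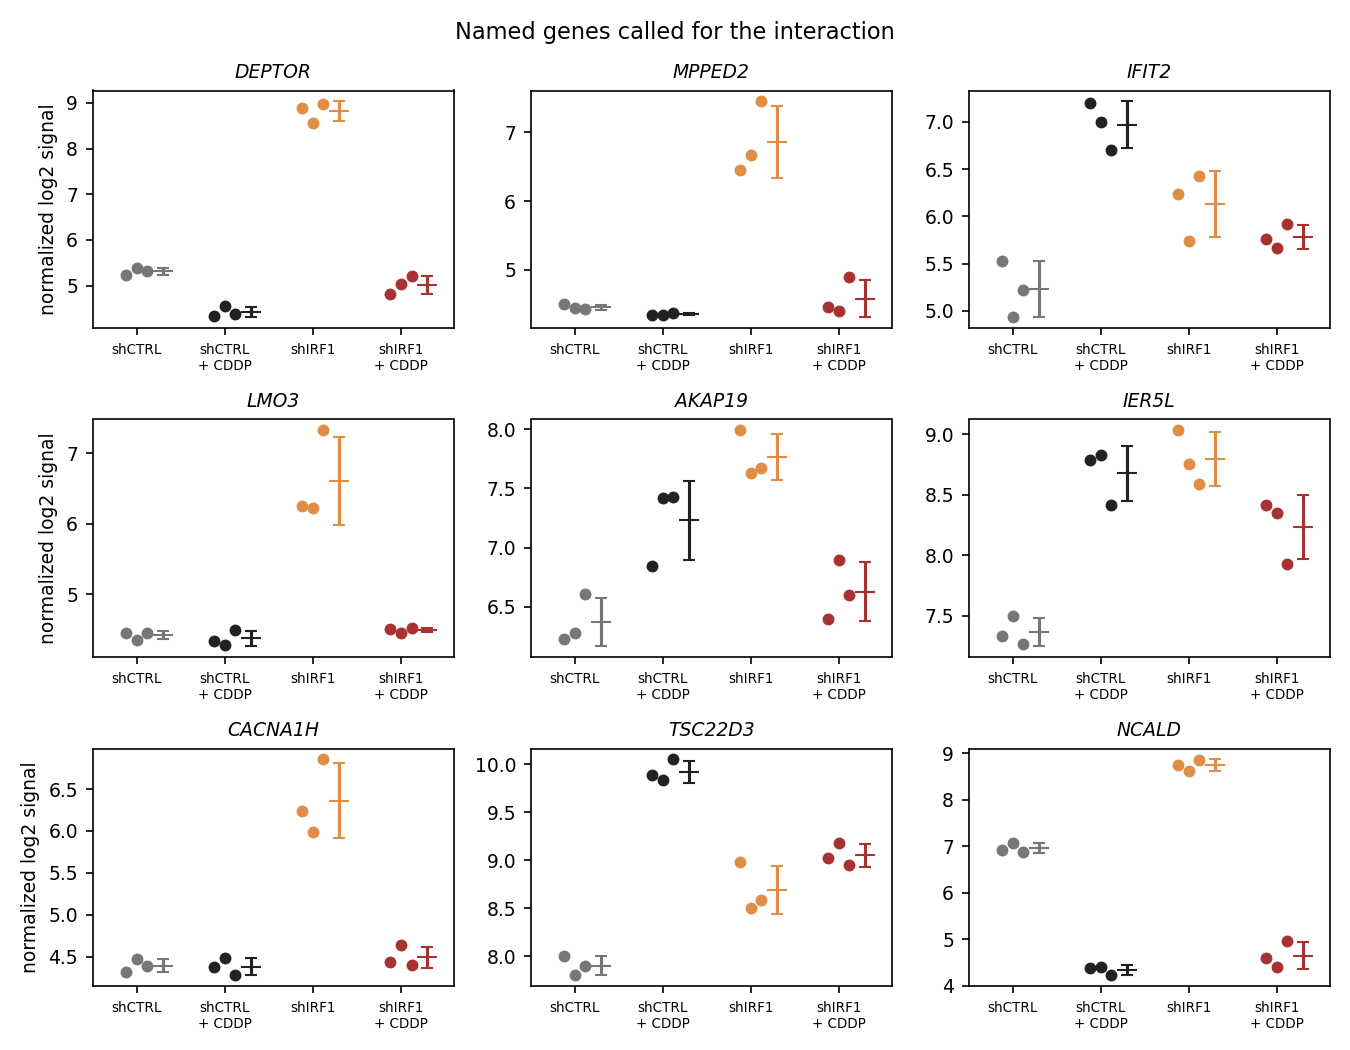
Log2 normalized signal on each of the 12 arrays for the 9 named genes called in the interaction, by group (points, with group means). IFIT2, AKAP19, IER5L and TSC22D3 were detected on all arrays, while the other 5 genes lie near the background in at least 1 group.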

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

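Sorting the other splits of the arrays by how they part the arms was chosen after their counts had been seen, while the other tests in this part were set beforehand.

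The test of the difference between the CDDP responses under the 2 shRNA labels called 12 features (limma, all with an adjusted p under 0.05). The 9 named genes among them had fitted interactions of log2 -2.90 (DEPTOR), -2.17 (MPPED2), -2.09 (IFIT2), -2.07 (LMO3), -1.995 (AKAP19), -1.88 (IER5L), -1.86 (CACNA1H), -1.66 (TSC22D3) and -1.48 (NCALD). For DEPTOR, MPPED2, LMO3, CACNA1H and NCALD, detected on 0 of 3 shCTRL arrays with CDDP, the fitted value is set by the background, and neither a difference nor its direction is established. The other 4 were detected on all 12 arrays, and of the 3 unnamed features 2 were. Of 100 splits of the arrays within the CDDP and no CDDP sets, the real one included, 9 gave at least 12 features, and the highest other gave 1906, so chance cannot be excluded for this count. Most of the larger counts point to a structure of the samples: 7 of the 8 other splits with as many part the arms in opposite ways, which turns the difference between the shRNA labels into an interaction. Of the splits, 48 part both arms alike, among which 1 other than the real one had as many (14), and 52 part them in opposite ways. The latter can carry the shRNA difference, so 9 of 100 is not a measure of chance alone. The count fell to 2 to 6 without any of shCTRL array 1 (3), shCTRL CDDP array 1 (3), shIRF1 CDDP array 1 (4), shCTRL CDDP array 2 (2), shIRF1 CDDP array 2 (6) or shCTRL array 3 (2).

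As lists, S phase and E2F target genes and mitosis genes had a CDDP response that lay higher on arrays labelled shIRF1 than under shCTRL, although no single member passed. Neither call held with an estimated correlation (adjusted p = 0.294 and 0.58), nor did those of the 6 lists that follow (adjusted p = 0.329, 0.227, 0.227, 0.294, 0.454 and 0.227, in the order given). The median interaction was 0.41 over 38 S phase genes, 35 of them positive (0 passed by limma, also adjusted over the list alone, with 7 at an unadjusted p under 0.05, camera adjusted p = 1.64e-07). Over 45 mitosis genes it was 0.34, with 42 positive (0 passed, also adjusted over the list alone, 3 unadjusted, camera adjusted p = 1.68e-06). Between the shRNA labels the S phase median was -0.46 without CDDP and -0.04 with it. The S phase interaction thus rests in large part on a lower level without CDDP on arrays labelled shIRF1. The mitosis medians were -0.16 and 0.17. Interferon-stimulated genes lay lower, with a median of -0.27 and 33 of 43 negative (1 passed, IFIT2, and 3 adjusted over the list alone, camera adjusted p = 0.000493). Described IRF-1 targets had a median of -0.39, with 14 of 19 negative (0 passed, also adjusted over the list alone, 2 unadjusted, camera adjusted p = 0.016), and histone genes -0.35, with 12 of 14 negative (0 passed, 1 adjusted over the list alone, 4 unadjusted, 0.00434). Cholesterol synthesis genes had -0.28 (14 of 19 negative, 0 passed, also adjusted over the list alone, 3 unadjusted, camera adjusted p = 0.0158), oxidative phosphorylation genes -0.16 (35 of 48, 0 passed, also adjusted over the list alone, 0 unadjusted, 0.017) and genes of the integrated stress and unfolded protein response -0.13 (17 of 25, 0 passed, 1 adjusted over the list alone, 8 unadjusted, 0.017). The other 17 lists had camera adjusted p of 0.055 (heat shock genes) to 0.957 (p53 targets).

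With an estimated correlation camera put 4 of the 25 lists at an unadjusted p under 0.05 in the interaction. Those adjusted p were the highest over the alternatives of each list. The lowest were 4.2e-11 for S phase genes, 2.94e-11 for mitosis genes, 2.94e-06 for interferon-stimulated genes, 0.00209 for IRF-1 targets, 2.9e-05 for histone genes, 0.000918 for cholesterol synthesis, 1.94e-05 for oxidative phosphorylation and 0.00146 for the integrated stress response. The mitosis call was lost without shCTRL array 2 (0.0746). The calls of IRF-1 targets, the integrated stress response and cholesterol synthesis were lost without shCTRL CDDP array 2 (0.0681 each), and those of the last 2 also without shIRF1 CDDP array 3 (0.0635 and 0.0805). The oxidative phosphorylation call was lost without shIRF1 CDDP array 1 (0.0593), shCTRL array 2 (0.0675), shCTRL CDDP array 3 (0.0582) or shIRF1 array 3 (0.0687).

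For the pairwise comparisons, 3 arrays against 3 make 10 splits, too few for a share under 0.05. Of these, 1 gave as many genes in each comparison, the real one. The real counts were 1051 and 692 for shIRF1 without and with CDDP, and 4849 and 3960 for CDDP in shCTRL and on arrays labelled shIRF1, and the highest of the other splits was 0 in each by limma, with at most 1037, 1685, 1180 and 1209 features at an unadjusted p under 0.05.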

How the results depend on the processing

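Leaving out the 2 arrays with the lowest weights together was chosen after the data were seen, and every other alternative was planned. Called list and named gene results kept their direction in the alternatives that gave them a value, except that mitosis genes in shIRF1 without CDDP turned from lower to higher without shCTRL array 2 (camera adjusted p = 0.577, within 3.22e-05 without shIRF1 array 2 to 0.753 with an estimated correlation over its alternatives). Of the 321 calls of named genes 203 had a value with detection at 0.01 on all 12 arrays and 312 with only the groups compared, and every probe as a feature and the stricter thresholds were run for the counts alone. The direction of IRF1 without CDDP, which never passed, ran from -0.09 to 0.24 with 1 array left out. Where no cause is given, the cause was not tested. Detected probes made up 38.2% to 44.7% per array, and for the others a change has only a bound or could not be read. The files used give no slide, so a slide block was not run.

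With median scaling in place of quantiles, calls numbered 499 and 310 for shIRF1 without and with CDDP (56.8% higher in the latter, in place of 42.8%), and 2983 and 2226 for CDDP in shCTRL (37.4% higher, in place of 50.0%) and on arrays labelled shIRF1. Features called the same way in both arms numbered 191 and 1664 in place of 360 and 2932, and the rise of IRF1 on arrays labelled shIRF1 was 0.79 (adjusted p = 0.0797). IRF1 with CDDP was called lower on arrays labelled shIRF1 without background correction (-0.75, 0.043), in the series matrix values (-0.84, 0.0343) and with a variance trend (-0.82, 0.0442), over a range of adjusted p from 0.0209 to 0.239. The series matrix gave 23 interaction calls. Without the detection filter, which tests more features, 7 lists were called for shIRF1 with CDDP and 10 for CDDP on arrays labelled shIRF1, where the rise of IRF1 was 0.78 (0.0692, within 0.014 to 0.107 over its alternatives). Detection at 0.01 on all 12 arrays left 5 interaction calls. With only the groups compared in the model, which has fewer residual degrees of freedom, 5 lists were called without CDDP and 329 features with it. Array weights gave 5 lists without CDDP and 19 interaction calls. At an adjusted p under 0.01, a stricter limit, calls numbered 498, 279, 3059, 2370 and 1 (the interaction), and 175 and 1802 were shared. With an estimated correlation camera called 1, 0, 4 and 0 lists for shIRF1 without and with CDDP, CDDP in shCTRL and the interaction (6, 4, 6 and 4 at an unadjusted p under 0.05), and fry called 16 and 13 lists for CDDP and 1, heat shock genes (adjusted p = 0.0122), for the interaction. With both arrays of lowest weight left out, 428 features and 7 lists were called for shIRF1 with CDDP, and 3 features in the interaction.

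With each array left out in turn, counts ran from 585 to 1167 and 356 to 728 for shIRF1 without and with CDDP, 3709 to 5000 and 2941 to 4177 for CDDP in shCTRL and on arrays labelled shIRF1, and 2 to 14 for the interaction. Lists called ran from 5 to 9, 3 to 8, 8 to 10, 6 to 8 and 5 to 9 in that order. Shared features ran from 245 to 349 and 2324 to 2943. The IRF1 change ran from -1.08 to -0.59 for shIRF1 with CDDP, 1.46 to 1.96 and 0.70 to 0.92 for CDDP, and -1.18 to -0.68 for the interaction. Of 35 list calls 23 kept their side of the threshold with any array left out, as did 236 of 321 calls of named genes. Under the other alternatives, fry included, 9 and 231 did. The ranges of adjusted p given for lists are those of camera and leave out fry, which tests a list against no change.

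The labels do not say that a replicate number marks a shared culture or day. Deviations from the group means correlated above 0.1 for 10 of 18 pairs of arrays with the same number (r = -0.028 to 0.237), and 10 of 12 arrays correlated best with their own number, a hint of pairing from the data. Since 8 pairs lay lower, the numbers were not taken to pair the arrays as a whole, although all 3 pairs of shCTRL with and without CDDP lay above 0.1 (0.183, 0.159 and 0.208). With the number as a block, calls numbered 1210, 835, 5226, 4294 and 13, lists 8, 4, 9, 6 and 8, and shared features 422 and 3182. The IRF1 changes were then 0.10 (limma adjusted p = 0.881), -0.82 (0.0614), 1.70 (0.000119), 0.78 (0.0252) and -0.92 (0.41). The block changed no list call, and of 544 named gene results 5 lost and 5 gained a call, none of them for CDDP in shCTRL. The NCALD interaction was among those lost (adjusted p = 0.0541, within 0.00568 to 0.53 over its alternatives).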

Other observations

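The tests over length-matched small RNAs and of the size of the shIRF1 differences with and without CDDP were chosen only after the results were seen, as were the small RNAs, PARN and gene span as subjects, an interval condition, a simulation and the division of shared arrays for PARN and the array pairs for gene span.

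Markers of ovarian and epithelial tumours moved both ways on arrays labelled shIRF1. The tight junction protein CLDN3 was higher without and with CDDP (log2 2.23 and 1.54, SE 0.26) and so was the adaptor GRB7 (1.82 and 1.41, SE 0.23), while the folate receptor FOLR1 was lower (-1.59 and -2.005, SE 0.26). A further FOLR1 probe changed by -0.36 and -0.61 (limma adjusted p = 0.589 and 0.266), and a further GRB7 probe by 0.37 with CDDP (0.479). Of 18 markers 4 rose and 2 fell without CDDP (5 and 3 adjusted over the list alone, camera adjusted p = 0.112), and 3 rose and 2 fell with it (4 and 2 adjusted over the list alone, 0.268). Metallothionein genes, whose proteins bind metal ions and which are close copies of each other, split without CDDP, MT1F (1.69) and MT1E (1.32) higher and MT1G (-1.28) and MT2A (-1.13) lower, 1 of 5 not passing (the same adjusted over the list alone, camera adjusted p = 0.965). With CDDP 2 rose (2 and 1 lower adjusted over the list alone, 0.305), and CDDP itself lowered 1 in shCTRL and 0 on arrays labelled shIRF1 (0.341 and 0.991).

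With CDDP the peptide hormone gene ADM rose by 2.62 in shCTRL and 3.06 on arrays labelled shIRF1 (SE 0.19), and the transcriptional regulator ID2 by 4.01 and 2.37 (SE 0.28). The drug exporter ABCC4 fell by 1.87 and 2.35 (SE 0.22) and the copper transporter ATP7A by 1.11 and 1.24 (SE 0.22). In crosslink repair FANCC fell by 1.85 and 1.19 (SE 0.19) and XRCC3 rose by 1.01 and 1.52 (SE 0.21). On arrays labelled shIRF1, CDH1 fell by 1.74 and SNAI2 rose by 1.63 with CDDP (SE 0.23 and 0.19). In shCTRL, where the rule did not name them, CDH1 also fell and SNAI2 also rose with CDDP. Neither was called in the interaction, so the change is not particular to the shIRF1 label. None of the lists these genes were drawn from was called with CDDP. In shCTRL and on arrays labelled shIRF1, 7 and 11 of 35 crosslink repair genes rose and 4 and 2 fell (7 and 13 higher, 4 and 2 lower adjusted over the list alone, camera adjusted p = 0.413 and 0.0752), 3 and 3 of 20 transport genes rose and 4 and 5 fell (5 and 5 lower adjusted over the list alone, 0.985 and 0.666), 6 and 6 of 25 hypoxia genes rose and 2 and 3 fell (the same adjusted over the list alone, 0.153 and 0.273), and 4 and 6 of 27 epithelial and mesenchymal genes rose and 8 and 6 fell (0.483 and 0.662). Apoptosis regulators (8 and 10 of 31 higher, 3 and 2 lower, 0.281 and 0.0752), heat shock genes (4 and 5 of 17 higher, 1 and 0 lower, 0.808 and 0.0752), NRF2 targets (1 and 3 of 16 higher, 3 and 4 lower, 0.985 and 0.828), interferon-stimulated genes (8 and 4 of 43 higher, 1 and 5 lower, 0.0585 and 0.858), cholesterol synthesis genes (3 and 0 of 19 higher, 0 and 2 lower, 0.428 and 0.584), cytosolic ribosomal proteins (3 and 2 of 65 higher, 1 and 0 lower, 0.608 and 0.662) and oxidative phosphorylation genes (2 and 1 of 48 higher, 0 and 1 lower, 0.341 and 0.669) were not called either.

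The remaining lists were not called between the shRNA labels, at camera adjusted p of 0.672 and 0.54 for p53 targets (4 of 26 higher and 2 lower without CDDP; by limma 0 with it, 7 at an unadjusted p under 0.05), 0.849 and 0.209 for AP-1 genes (3 and 2 of 21; 0 with, 6 unadjusted), 0.849 and 0.0673 for the integrated stress response (2 and 1 of 25; 0 with, 6 unadjusted), 0.268 and 0.2 for NRF2 targets (1 and 3 of 16 lower), 0.62 and 0.807 for cisplatin transport (1 of 20 higher; 0 with, 2 unadjusted), 0.479 and 0.207 for apoptosis regulators (3 of 31 higher and 1 lower, 1 higher with), 0.849 and 0.665 for hypoxia genes (2 and 2 of 25, 1 lower with), 0.448 and 0.308 for heat shock genes (1 and 1 of 17; 0 with, 3 unadjusted), 0.894 and 0.964 for ribosomal proteins (0 of 65, 4 and 2 unadjusted) and 0.453 and 0.207 for oxidative phosphorylation (0 of 48, 0 and 2 unadjusted). With CDDP, 1 of 38 S phase genes fell (0.308), 1 of 35 crosslink repair genes rose (0.593), 2 of 21 NF-kB genes rose (0.268) and 1 of 19 cholesterol genes rose (0.305). Markers of other cell types gave no called list. Of 3 fibroblast markers COL1A1 was lower without CDDP (-1.31, SE 0.23, list adjusted p = 0.512), of 7 leukocyte markers 1 was lower on arrays labelled shIRF1 in each arm (0.564 and 0.209) and CD14 rose with CDDP in shCTRL (1.22, SE 0.24, 0.457), and 0 of 2 endothelial markers passed in any pairwise comparison (0.517 to 0.991, 0 also unadjusted). Adjusted over the list alone, the counts of the 73 uncalled pairwise list results moved by at most 3 genes, for AP-1 genes with CDDP (1 higher and 3 lower). For 13 of the 73 the median, the mean and the direction of the test differ in sign, with a median of at most 0.23 in size.

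A pattern that was noticed and then tested is the rise of small RNAs on arrays labelled shIRF1, where 8 and 9 of 17 SCARNA genes rose without and with CDDP (medians 0.84 and 0.83) and 15 of 62 SNORA genes in each arm (0.28 and 0.43), medians that stayed above 0 under each scaling (0.13 to 0.89). A rise in the mRNA of protein-coding host genes is argued against for 26 of 38 called small RNAs, those within the span of a tested gene. Of the 23 tested hosts 0 was called higher by limma (0 and 2 at an unadjusted p under 0.05), and their medians were 0.043 and -0.083. Hosts were assigned by span without regard to strand, and noncoding hosts were not looked at. For the other called small RNAs expression from a host stays open. A preparation that kept more small RNA stays open: over 19 other small RNAs of matching length the medians were 0.46 and 0.20 (95% bootstrap interval -0.30 to 0.55 for the latter), a test that took the place of 1 over all 80 others (0.13 and 0.0053), first read as arguing against it, after that value showed the need to match lengths. Of 19 genes of RNA processing looked at afterwards, limma called 2 lower: PARN, which trims tails that an oligo(dT) primed kit could read, without CDDP (2.68-fold, -1.42, SE 0.24, adjusted p = 0.00212) and with it (-1.22, 0.0101), and the exosome subunit EXOSC3 without it (2.08-fold, -1.06, SE 0.15, 0.000463, against -0.48, 0.0929 with it), of which PARN alone was tested as an explanation. A lower PARN level stays open. The rank correlations across 79 genes set as its test were 0.023 and 0.094 (intervals -0.20 to 0.26 and -0.13 to 0.31). Both lay under 0.1, which by the rule set beforehand would argue against a lower PARN level. Conditions added after the values were seen leave it open: the intervals, and the values with shared arrays divided, did not stay under 0.1. The correlations pair comparisons that share 3 arrays with opposite sign. That alone gave -0.471 and -0.474 in simulated unchanged groups (95% of draws -0.633 to -0.285 and -0.647 to -0.276). The observed values lay above these ranges. The simulation held no changed genes, while many of the 79 changed, so this does not speak for PARN. With the shared arrays divided between the comparisons the observed correlations were 0.054 to 0.225 and 0.101 to 0.310. CDDP, which also changed many other genes, lowered PARN more (5.05-fold in shCTRL and 4.39-fold on arrays labelled shIRF1). Beside this fall the SCARNA medians were smaller (0.35 and 0.44) and the SNORA medians of similar size (0.23 and 0.33). The medians thus did not follow the PARN mRNA level alone, but PARN protein was not measured.

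A further hypothesis is that the fall of genes with CDDP follows their length, as blocked elongation on crosslinked DNA might give. The rank correlation of gene span and change was -0.499 in shCTRL and -0.438 on arrays labelled shIRF1, under the -0.2 set before it was computed, and between -0.513 and -0.430 under each scaling. Signal level as the cause is argued against, since within 5 bins of mean signal the correlation in shCTRL was -0.605 to -0.356. A length trend between any arrays is argued against too: the shIRF1 comparisons gave -0.056 and 0.118, the latter past the bound of 0.1 set beforehand and opposite in sign, and single arrays with and without CDDP gave -0.480 to -0.354 over 18 pairs, against -0.134 to 0.196 over 12 pairs within groups, a criterion added afterwards. Whether RNA quality, which was not measured here, moved with CDDP stays open, and so does any property that goes with gene span.

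That 1051 features differed on arrays labelled shIRF1 without CDDP while IRF1 did not (0.10, interval -0.43 to 0.62) is a pattern to follow up. A mislabelled array is argued against, since 12 of 12 arrays scored on the side of their own label over genes chosen without them (-0.020 to 0.119 for shCTRL and 0.890 to 1.02 for arrays labelled shIRF1). If the IRF1 transcript level set the differences, they could be expected to grow with CDDP, where IRF1 lay lower on arrays labelled shIRF1, but the ratio of the mean squares with CDDP to those without was 0.937. It ran from 0.829 without shIRF1 CDDP array 1 to 1.13 without shIRF1 CDDP array 2, so this stays open. Clonal or culture differences between the cells that carry each shRNA were not tested and stay open.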
